A study of Homo sapiens with 6 samples.

How the data were processed

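HG3 cells, an established human B-cell chronic lymphocytic leukaemia line, were stained for CXCR4 and CD18 and sorted into single-positive populations, named by the labels as representing high and low survivorship. Per the labels' protocols, 3 biological replicates were collected over 2 weeks, 400 ng of total RNA entered a stranded mRNA kit that selects polyadenylated RNA, and the pooled libraries were sequenced on an Illumina NextSeq. Groups and replicate numbers (time points 1 to 3) came from the sample titles.

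The deposited file of each library held RSEM estimates per gene. Per the file headers these were expected counts, which are estimated read counts that need not be whole, and TPM, which is scaled to gene length and to one fixed total per library; the deposited FPKM values were not used. The submitters' processing notes name cutadapt, Bowtie2, Subread, featureCounts, RSEM and the GRCh38 build, without versions. The annotation release, the RSEM version and the strand setting are not given in the sources used here, so genes that overlap another gene on the opposite strand were treated as uncertain. RSEM divides reads that match several genes by estimated shares, so a gene with fractional expected counts shares reads with another gene. Between 8.70% and 9.18% of rows per library were not whole, and a gene was called partly shared where any library's expected count differed from a whole number.

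Each file held 56292 rows: 56200 genes and 92 spike-in controls, which had 0 reads in all 6 libraries and were left out. Of the gene identifiers, 55893 matched GENCODE 29 by stable identifier, which supplied symbols, types and GRCh38 coordinates, and 307 did not. Expected counts were rounded to whole numbers. The libraries held between 56301071 and 69957542 expected counts, all of them in gene rows. No 2 libraries held identical values, and the chi-square per degree of freedom over genes lay between 56.7 and 248.6 within groups, above the value near 1 that 2 files of 1 library would give. That the 3 libraries of a group are biological replicates rests on the labels. Intervals and floors (3 counts over a group) cover counting error only, because reads carry no molecular identifiers.

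The comparison was high minus low survivorship in all 6 libraries, with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter (18476 genes left), a quasi-likelihood fit without a block, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are TMM-normalised, and the SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. Named genes were fixed by a rule: both sort markers; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM over the 6 libraries, groups that do not overlap and a gene symbol, leaving out sex-linked Y genes and XIST, antigen receptor segments and clone-named genes; the 3 members with the smallest p-value of each list of at least 5 tested members; and the 5 further genes with the smallest p-values. The text leaves out 1 gene that the rule selects. Of the named genes, PRRX1, IL18RAP, OPCML-IT1, PLEKHA5, DAPK1, TAPBPL, HERPUD1, EGLN3, TM7SF2, UTP4, PPAN, MT-ATP8 and MT-CO3 overlap a tested gene on the same strand. ROR1, GPR18, BCL2L11, XRCC1, TYMS, HLA-F, JCHAIN, GCSAM, HSPD1, CHORDC1, VLDLR, CA9, STARD4, BOP1, RPL28 and CD68 overlap one on the other strand, as do those named with the largest changes, so part of the reads of these genes is uncertain. Groups of 3 against 3 fail to overlap by chance for 10% of unchanged genes. Genes named outside the rule were chosen after their values were seen: RFXAP, CD28, CD3E, LCK, TRAC, the natural killer, fibroblast and platelet markers, and the further genes of the closing section.

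Of 37 gene lists, 33 had at least 5 tested members and were tested with camera of limma 3.58.1 (log2 CPM with a prior count of 2, preset correlation 0.01), with an estimated correlation, and with fry. The lists covered B-cell identity, CLL markers, B-cell receptor signalling, NF-kB targets, interferon-stimulated genes, integrins and adhesion, chemokine and sphingosine-1-phosphate receptors, Wnt and Notch pathways, apoptosis, p53 targets, DNA repair, nucleoside handling, S and G2/M phases, MHC classes I and II, plasma cell, germinal centre, B-cell activation and memory, immediate early, heat shock, unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis, mitochondrial and ribosomal protein genes, chromatin and CLL driver genes, and T-cell and myeloid markers. The sort markers and the natural killer, fibroblast and erythroid or platelet markers were reported by value.

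The titles give a time point number that marks a shared collection. Deviations from group means of equally numbered libraries correlated at 0.616, 0.465 and 0.33 across genes, each library's highest correlation with the other group being that of its own number, so the numbers pair the samples and the fit with collection as a block is printed wherever it ended or made a call or moved a count by over 1.5 times. The first principal component of log2 CPM held 80.0% of the variance and parted the groups, and the next held 11.6%.

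The main fit, the gene lists, the rule for named genes and most alternatives were set before the data were examined: RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, the block, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), DESeq2 1.42.0, an estimated correlation, fry, and leaving out each library and each collection. Added after seeing the data were fits without mitochondrial and ribosomal protein genes, with a length and GC correction (with and without the block), on genes with whole expected counts only, and list tests with the block and an estimated correlation or fry. Counts drawn from the real means for 18476 genes, 200 of them changed, were used to test the fit on simulated data for this comparison. It recovered 3% of genes changed 1.5-fold, 32.8% of those changed 2-fold and 93.9% of those changed 4-fold, and called 9 of 18276 unchanged genes. The window scan of the closing section was also tested on simulated data.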

Results

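RNA from sorted subpopulations of HG3, a cell line derived from B-cell chronic lymphocytic leukaemia (CLL), was measured by stranded mRNA sequencing. Cells positive for CXCR4 alone stood for a subpopulation of high survivorship, and cells positive for CD18 alone for one of low survivorship. CXCR4 is the receptor of the chemokine CXCL12, and CD18 is the integrin beta 2 chain encoded by ITGB2. Each sort was collected at 3 time points over 2 weeks, which gave 3 libraries per group and 6 in all. The stained populations carried the names TP0 and TP1, and the labels do not say which gate was drawn from which population. The source population and the gate can therefore not be separated here. The libraries held 56301071, 61358009 and 69957542 expected counts in the high survivorship group and 62638936, 63048337 and 57424472 in the low survivorship group. Transcripts of the mitochondrial genome took 14.5% ± 3.60 (SD, n = 3) of the counts in the high survivorship libraries and 10.3% ± 2.78 (SD, n = 3) in the low survivorship libraries.

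The comparison asked which genes differed in expression between the sorted cells of high and low survivorship. The high survivorship cells carried more mRNA of the CLL surface marker CD5, of the T-cell-associated genes ICOS and TRAT1, of the interleukin 18 receptor subunit IL18RAP and of the transcription factor PRRX1. They carried less mRNA of ROR1, the ecto-nucleotidase NT5E (CD73), the toll-like receptor gene TLR3 and CD180, a toll-like receptor homologue. Also lower was mRNA of the pro-apoptotic BCL2L11 (BIM) and the antigen presentation gene HLA-DOA. Of 52 G2/M genes, 32 rose in the high survivorship cells, and 13 of 18 MHC class II genes fell. Of 18476 genes tested, 5552 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2468 higher and 3084 lower in the high survivorship cells. Of these, 3784 changed at least 2-fold (1695 higher and 2089 lower).

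The fit with collection as a block called 9690 genes (4770 higher and 4920 lower) and held 5551 of the 5552 calls in the same direction. Without the first collection 6077 genes were called, without the second 3634, and without the third 2292, of which 2244 changed at least 2-fold.

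The genes of both sort markers followed the gates. CXCR4 (ENSG00000121966.6; chromosome 2, 136114349 to 136118165, GRCh38) stood at 248.5 ± 52.7 CPM (SD, n = 3) in the high survivorship libraries and 17.9 ± 5.95 CPM in the low survivorship libraries, a log2 fold change of 3.79 (SE 0.29, edgeR adjusted p = 5.91e-05). ITGB2 (ENSG00000160255.17; chromosome 21, 44885953 to 44931989) stood at 1.67 ± 0.551 and 198.4 ± 4.795 CPM, a log2 fold change of -6.89 (SE 0.28, edgeR adjusted p = 6.16e-06). Because the cells were gated on these proteins, the values check the labels and are no finding.

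Among genes with a symbol and a mean of at least 5 CPM over the 6 libraries, the largest rise was that of PRRX1 (ENSG00000116132.11; chromosome 1, 170662728 to 170739419), a homeobox transcription factor of mesenchymal cells, from 0.0489 ± 0.0167 to 30.2 ± 8.09 CPM (log2 fold change 9.22, SE 0.36, edgeR adjusted p = 6.16e-06). TRAT1, an adaptor of the T-cell receptor complex, rose by 8.56 on the log2 scale (SE 0.46), from 0.0275 ± 0.0248 to 10.9 ± 1.199 CPM. CYP26B1, which degrades retinoic acid, rose by 8.37 (SE 0.92), with 42.5, 7.81 and 27.3 CPM in the 3 high survivorship libraries. DSCAM and TENM3, cell adhesion molecules of neurons, rose by 8.32 (SE 0.30) and 8.27 (SE 0.49). IL18RAP (chromosome 2, 102418689 to 102452565) rose from 0.322 ± 0.132 to 93.3 ± 15.1 CPM (log2 fold change 8.18, SE 0.32, edgeR adjusted p = 6.16e-06). MAPK10, the kinase JNK3, rose from 0.242 ± 0.0531 to 59.2 ± 5.45 CPM, and the translation termination factor gene GSPT2 from 0.102 ± 0.0359 to 22.4 ± 1.94 CPM. The sulfotransferase gene CHST4 rose by 7.70 (SE 0.40) and OPCML-IT1 by 8.32 (SE 0.39). OPCML-IT1 is an RNA on the same strand as its host gene OPCML and reads may be split between both.

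Among the same genes the largest fall was that of CD180 (ENSG00000134061.5; chromosome 5, 67179613 to 67196799), a toll-like receptor homologue of B cells, from 29.3 ± 16.1 CPM in the low survivorship libraries to 0.0685 ± 0.0488 in the high survivorship libraries (log2 fold change -8.67, SE 0.61, edgeR adjusted p = 4.13e-05). SUCNR1, the succinate receptor, fell from 78.6 ± 29.1 to 0.201 ± 0.0288 CPM (log2 fold change -8.61, SE 0.37). FFAR2, a receptor of short-chain fatty acids, fell from 41.2 ± 7.73 to 0.154 ± 0.179 CPM. TLR3 (chromosome 4, 186069152 to 186088069), a sensor of double-stranded RNA, fell from 53.6 ± 9.73 to 0.267 ± 0.143 CPM (log2 fold change -7.61, SE 0.37, edgeR adjusted p = 1.04e-05). The log2 fold change was -8.48 for PPP1R26, -8.38 for ANGPTL2, and -7.73 for RAPGEF5, an exchange factor for Rap GTPases. It was -7.71 for CLEC2D, the ligand of the natural killer cell receptor CD161, -7.58 for ZNF558 and -7.39 for SORBS2, with SE between 0.24 and 0.54. The next genes by p-value were SLITRK1, IRAK3, TNFRSF11A (the receptor RANK) and PRICKLE2, which rose by 7.10, 5.56, 6.87 and 7.67, while PLEKHA5 had a log2 fold change of -5.86. Reads of CLEC2D, ZNF558 and IRAK3 were partly shared with other genes. MAPK10, CHST4, PPP1R26, ANGPTL2, ZNF558, SORBS2, IRAK3, PRICKLE2 and ITGB2 overlap a tested gene on the other strand, so part of their reads is uncertain.

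**Figure D1:**
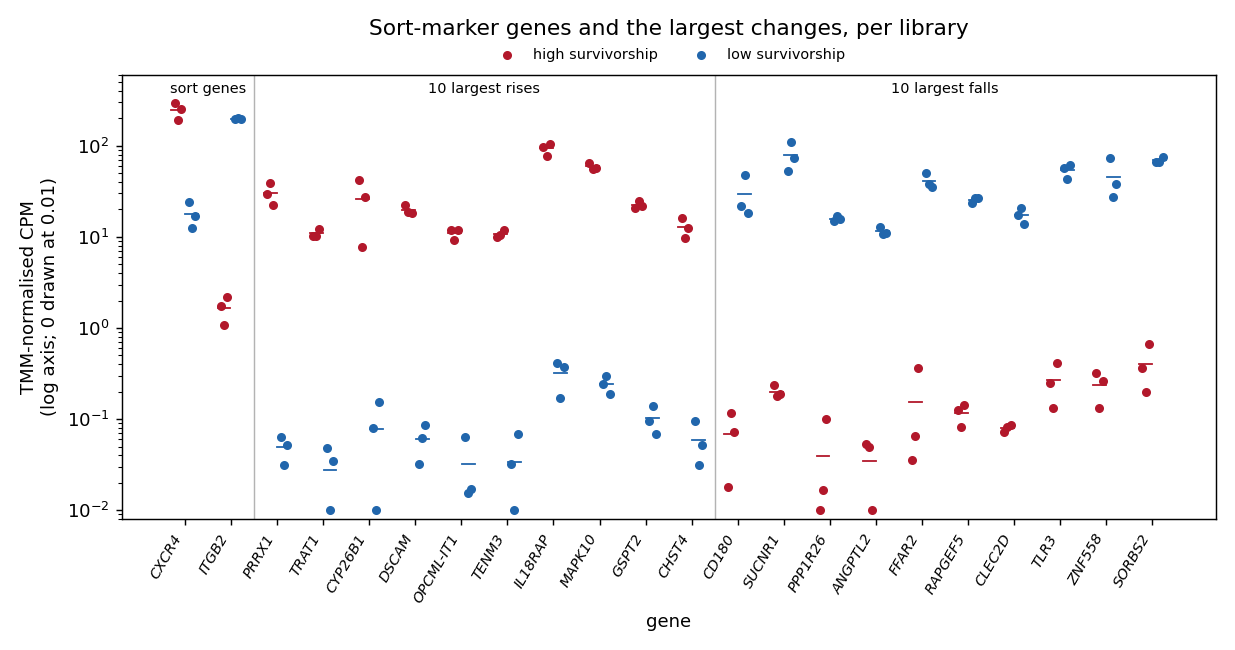
Expression of the sort-marker genes and of the 10 largest rises and 10 largest falls by the rule of the text in each library, as TMM-normalised CPM on a log axis with 0 drawn at 0.01. Points are libraries (3 high survivorship, 3 low survivorship) and bars are group means. No gene's groups overlap, which the rule required of the rises and falls. CYP26B1 spread from 7.81 to 42.5 CPM within the high survivorship libraries.

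**Figure D2:**
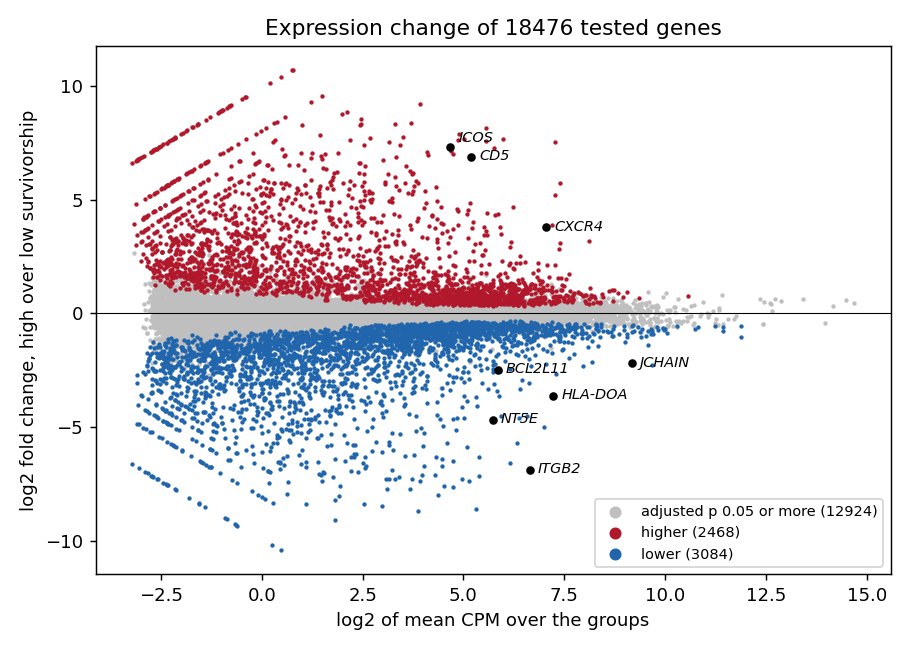
Log2 fold change (high over low survivorship) of the 18476 tested genes against the log2 of the mean CPM. Red points are the 2468 genes called higher, blue points the 3084 called lower, grey points the genes not called, and black points mark named genes such as CXCR4 at 3.79 and ITGB2 at -6.89.

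Among CLL markers, 8 of 14 tested genes rose and 3 fell (9 and 4 with the block), and camera did not call the list as a whole (adjusted p = 0.148). CD5 (chromosome 11, 61102395 to 61127852), whose protein on B cells is a diagnostic feature of CLL, rose from 0.607 ± 0.304 to 72.4 ± 14.1 CPM (log2 fold change 6.89, SE 0.36, edgeR adjusted p = 1.3e-05). ROR1 (chromosome 1, 63774022 to 64181498), a WNT5A receptor expressed on CLL cells, fell from 24.1 ± 3.91 to 1.14 ± 0.185 CPM (log2 fold change -4.40, SE 0.22). SEPT10, whose reads were partly shared, rose by 4.60 (SE 0.34). Of 22 B-cell identity genes, 4 rose and 10 fell (6 and 12 with the block). The Fc receptor-like genes FCRL1, FCRL2 and FCRL3, which modulate B-cell receptor signals, rose by 6.34 (SE 0.43), 4.58 (SE 0.27) and 6.16 (SE 0.41). The list had a camera adjusted p of 0.504. In the B-cell receptor pathway 5 of 24 genes rose and 6 fell (7 and 8 with the block). The ubiquitin ligase gene CBLB rose by 1.58 (SE 0.14) and the calcineurin-regulated factor NFATC2 by 1.49 (SE 0.27). The phosphatase gene PTPN6 (SHP-1) had a log2 fold change of -1.43 (SE 0.16). Germinal centre genes went both ways, with 7 of 16 higher and 4 lower (8 and 5 adjusted over the list alone). MME (CD10) and GCSAM rose by 5.86 (SE 0.48) and 2.83 (SE 0.27). Of 20 plasma cell genes 3 rose and 8 fell (3 and 9 adjusted over the list alone, 6 and 11 with the block). JCHAIN, the joining chain of polymeric antibodies, fell from 946.5 ± 160.0 to 207.7 ± 40.6 CPM. TXNDC5, a disulfide isomerase, fell from 399.1 ± 55.4 to 143.8 ± 13.3 CPM, and the elongation factor gene ELL2, with partly shared reads, rose by 2.21 (SE 0.23). Of 21 genes of B-cell activation and memory 4 rose and 6 fell (5 and 6 adjusted over the list alone, 7 and 6 with the block). Among them were FCRL5 at -3.31 (SE 0.27), ZEB2 at -4.13 (SE 0.40) and TBX21 at -1.90 (SE 0.26).

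For proliferation, 32 of 52 G2/M genes rose and 1, GAS2L3, fell (43 and 1 adjusted over the list alone), with a median log2 fold change of 0.93. Examples were TUBB4B, a tubulin with partly shared reads, from 78.8 ± 3.99 to 160.9 ± 11.1 CPM, and CKS2, a cofactor of cyclin-dependent kinases, from 38.5 ± 4.38 to 71.1 ± 3.45 CPM. GAS2L3, a cytoskeletal linker, had a log2 fold change of -6.16 (SE 0.60). Camera with a preset correlation of 0.01 gave the list an adjusted p of 7.11e-08, and the adjusted p = 0.978 with an estimated correlation. Of 41 S phase genes 3 rose, UNG, TYMS and HELLS, and none fell (0 and 0 adjusted over the list alone, 33 and 3 with the block). Their list median was 0.56 with a camera adjusted p of 0.00723, and the adjusted p = 0.978 with an estimated correlation. The S phase list call ended without the first low survivorship library (median 0.315, adjusted p = 0.122). The call of UNG ended without the third high survivorship library (edgeR adjusted p = 0.0604). Those of TYMS and HELLS each ended on leaving out any 1 of 3 libraries, the second high, the third high or the second low survivorship library (up to 0.133 and 0.126). The fits that leave out a library had no block. With all libraries and the block, the edgeR adjusted p was 4.65e-05 for UNG, 8.68e-05 for TYMS and 4.85e-05 for HELLS. Of 44 DNA repair genes 8 rose and 1 fell (26 and 4 with the block). They included the ubiquitin ligase gene RNF168 at 0.70 (SE 0.12), the damage recognition gene XPA at 0.63 (SE 0.15), and XRCC1, the scaffold of single-strand break repair, at -0.79 (SE 0.14). That of XPA ended without the third high or the third low survivorship library (edgeR adjusted p = 0.0569 and 0.0685). The DNA repair list had a camera adjusted p of 0.0249, and the adjusted p = 0.978 with an estimated correlation. The call ended without the third high survivorship library (0.0516) or the first low survivorship library (median 0.175, adjusted p = 0.151).

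Of 55 ribosomal protein genes 12 fell and 0 rose (9 and 0 adjusted over the list alone, 44 and 0 with the block), with a median log2 fold change of -0.42. RPS12 fell from 976.2 ± 100.3 to 487.2 ± 58.0 CPM. RPS27 had a log2 fold change of -0.997 (SE 0.22) and RPL28 of -0.81 (SE 0.19). Both calls ended without the third high survivorship library (edgeR adjusted p = 0.0541 and 0.0595). Reads of all 3 genes were partly shared with other genes. The camera adjusted p was 3.42e-05, and the adjusted p = 0.978 with an estimated correlation. Of the 13 tested genes of the mitochondrial genome, 1, MT-ATP8, rose (0 adjusted over the list alone, 6 with the block), with a list median of 0.52. MT-CYB stood at 6424 ± 1755 and 4085 ± 919 CPM and MT-CO3 at 13182 ± 4019 and 8581 ± 614 CPM in the high and low survivorship libraries (edgeR adjusted p = 0.109 and 0.111; 0.0117 and 0.0304 with the block). Reads of MT-CO3 were partly shared. The mitochondrial list was called by camera at 0.0408, not with the block (0.0516), and the adjusted p = 0.978 with an estimated correlation. That call and the call of MT-ATP8 each ended on leaving out any 1 of 4 libraries, the first or second high or the second or the third low survivorship library (up to 0.161 and 0.0879). The list median was 0.321 without the second and 0.797 without the first low survivorship library. Of 35 nuclear oxidative phosphorylation genes 3 rose and 3 fell (1 and 2 adjusted over the list alone, 12 and 5 with the block). Log2 fold changes were 1.18 (SE 0.15) for COX8A, -0.64 (SE 0.11) for NDUFB5 and -0.80 (SE 0.15) for UQCRB, with partly shared reads. Of 30 MYC-related ribosome biogenesis genes 2 rose and 1 fell (0 and 0 adjusted over the list alone, 9 and 3 with the block). These were BOP1 at 0.49, UTP4 at 0.42 and PPAN at -0.60, and each call ended on leaving out any 1 of 5 libraries, for UTP4 and BOP1 all but the second low and for PPAN all but the first high survivorship library (edgeR adjusted p up to 0.118, 0.135 and 0.143).

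For antigen presentation, 13 of 18 MHC class II genes fell and 1, RFXAP, rose (14 and 1 adjusted over the list alone), with a median log2 fold change of -0.79. HLA-DOA (chromosome 6), a chain of the HLA-DO peptide-loading modulator, fell from 277.4 ± 40.9 to 22.6 ± 3.18 CPM (log2 fold change -3.62, SE 0.18, edgeR adjusted p = 1.11e-05). HLA-DOB had a log2 fold change of -2.31 (SE 0.31) and HLA-DMB, a chain of the loading catalyst HLA-DM, of -1.63 (SE 0.18). The list's camera adjusted p was 0.000128, and the adjusted p = 0.978 with an estimated correlation. Of 20 MHC class I genes 7 fell and 0 rose (8 and 0 adjusted over the list alone, 11 and 0 with the block). HLA-E and HLA-F, with partly shared reads, had log2 fold changes of -1.38 each (SE 0.17 and 0.18), as had TAPBPL, a peptide editor (SE 0.18). The class I list had a camera adjusted p of 0.0356, and the adjusted p = 0.797 with an estimated correlation. The call ended without the second high survivorship library (0.0614) or the second low survivorship library (0.072). Of 33 interferon-stimulated genes 10 fell and 2 rose (15 and 7 with the block), with a camera adjusted p of 0.385 for the list. Among them were the antiviral genes OAS1 at -1.35 (SE 0.14) and BST2 at -0.92 (SE 0.12), and STAT2 at -0.82 (SE 0.12).

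On homing and adhesion, the chemokine and sphingosine-1-phosphate receptor list had 19 tested genes, CXCR4 left out. Of these, 4 rose and 7 fell (4 and 9 adjusted over the list alone, 4 and 12 with the block). The list had a camera adjusted p of 0.0941. CCR6, the CCL20 receptor, with partly shared reads, fell from 59.8 ± 1.70 to 4.79 ± 0.660 CPM. S1PR4 had a log2 fold change of -1.43 (SE 0.12). GPR18, on the list though not a chemokine or sphingosine-1-phosphate receptor, had one of -3.84 (SE 0.34). Of 29 integrin and adhesion genes, ITGB2 left out, 5 rose and 9 fell (7 and 9 adjusted over the list alone, 10 and 11 with the block). ITGA5, the fibronectin receptor alpha chain, rose from 1.27 ± 0.219 to 31.4 ± 3.88 CPM. ITGA9 fell from 38.7 ± 7.03 to 0.277 ± 0.122 CPM, and ITGB5 had a log2 fold change of -3.05 (SE 0.21). Of 26 Notch pathway genes 9 rose and 2 fell (9 and 4 adjusted over the list alone, 10 and 7 with the block). The ligand gene JAG1 rose from 3.38 ± 0.681 to 23.5 ± 2.20 CPM. NOTCH2, with partly shared reads, rose by 2.81 (SE 0.26), and PSEN2, a gamma-secretase subunit, had a log2 fold change of -2.06 (SE 0.25). Of 29 Wnt pathway genes 7 rose and 9 fell (11 and 12 with the block). They included the repressor gene TLE1, partly sharing reads, at 3.76 (SE 0.15), ROR1 at -4.40 and the receptor gene FZD7 at -4.05 (SE 0.24). Of 25 NF-kB target genes 4 rose and 2 fell (3 and 2 adjusted over the list alone, 15 and 2 with the block). CCL22 and EBI3 rose by 1.27 (SE 0.22) and 1.03 (SE 0.17). LTA, lymphotoxin alpha, fell from 18.2 ± 5.58 to 0.461 ± 0.242 CPM (log2 fold change -5.27, SE 0.41). The Notch, Wnt, integrin and NF-kB lists had camera adjusted p-values of 0.21, 0.847, 0.852 and 0.13.

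For cell death and drug handling, 4 of 24 pro-apoptotic genes rose and 4 fell (7 and 7 with the block). BCL2L11 (chromosome 2, 111119378 to 111168447), the BH3-only protein BIM, fell from 98.3 ± 14.2 to 17.7 ± 5.11 CPM (log2 fold change -2.47, SE 0.23, edgeR adjusted p = 0.000149). CASP10 had a log2 fold change of -1.02 (SE 0.14), and DAPK1 rose by 1.21 (SE 0.19). Of 14 anti-apoptotic genes 2 rose and 1 fell (6 and 2 with the block). These were BCL2A1, with partly shared reads, at 0.81 (SE 0.16), BIRC5, survivin, at 0.96 (SE 0.22) and BCL2L10 at -0.86 (SE 0.16). The BIRC5 call ended without the third high survivorship library (edgeR adjusted p = 0.0571). Of 29 p53 target genes 5 rose and 4 fell (12 and 6 with the block). PHLDA3, an inhibitor of AKT, rose from 0.295 ± 0.0811 to 19.4 ± 4.13 CPM. FDXR rose by 0.97 (SE 0.15), and the decoy receptor gene TNFRSF10C had a log2 fold change of -2.47 (SE 0.36). Of 19 genes that handle nucleosides and their analogue drugs 3 rose and 4 fell (7 and 6 with the block). NT5E, which makes extracellular adenosine, fell from 102.2 ± 25.8 to 3.99 ± 0.396 CPM. ABCB1, the drug efflux pump P-glycoprotein, with partly shared reads, rose from 5.01 ± 1.65 to 24.5 ± 6.57 CPM. CDA, cytidine deaminase, had 1 count over the high survivorship libraries and 444 over the low survivorship libraries, a normalised ratio of 445.8 with an exact 95% counting interval of 79.6 to 17600. Of 24 chromatin modifier and CLL driver genes 1 rose and 4 fell (7 and 4 with the block). They included HDAC9 at -2.04 (SE 0.30) and DNMT3A at -0.77 (SE 0.14), both partly sharing reads, and MYD88 at -0.695 (SE 0.13). Camera adjusted p-values of these 5 lists, in the order given, were 0.985, 0.702, 0.497, 0.823 and 0.985.

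Among stress and metabolic lists, edgeR called 0 of 18 heat shock genes (3 at an unadjusted p under 0.05; 6 rose and 2 fell with the block). DESeq2 called 2 and limma-voom 1. HSPD1, CHORDC1 and HSPB1, with partly shared reads, had log2 fold changes of -0.56, 0.75 and 0.59 (edgeR adjusted p = 0.0535, 0.0563 and 0.0997, and with the block 0.00136, 6.81e-05 and 0.000337). Of 26 immediate early genes 3 rose and 4 fell (8 and 6 with the block). They included the phosphatase gene DUSP4 at 2.11 (SE 0.17), and FOSL2 at 1.28 (SE 0.23). KLF2, a regulator of lymphocyte trafficking, fell from 19.9 ± 1.95 to 1.78 ± 0.337 CPM. Of 25 unfolded protein response genes 2 rose and 4 fell (1 and 3 adjusted over the list alone, 6 and 9 with the block). They included VLDLR at 2.17 (SE 0.25), XBP1 at -0.86 (SE 0.19) and HERPUD1 at -1.10 (SE 0.28). The call of HERPUD1 ended without the third high (edgeR adjusted p = 0.0611) or the second low survivorship library (0.0565). Of 31 hypoxia and glycolysis genes 1, CA9, rose and 1, EGLN3, fell (16 and 3 with the block). CA9 (carbonic anhydrase 9) stood at 23.5 ± 20.6 and 0.262 ± 0.218 CPM, with 44.4, 3.25 and 23.0 CPM in the high survivorship libraries. EGLN3 had a log2 fold change of -2.30 (SE 0.25). PFKFB3 stood at 31.9 ± 4.46 and 40.7 ± 4.92 CPM (edgeR adjusted p = 0.1275, 0.00454 with the block). Camera called this list with the block (adjusted p = 0.0221) and not without it (0.462), and the adjusted p = 0.9952 with the block and an estimated correlation. Of 23 cholesterol synthesis genes 2 rose and 3 fell (2 and 2 adjusted over the list alone, 6 and 9 with the block). They included NSDHL at 0.98 (SE 0.17), TM7SF2 at -1.32 (SE 0.21) and STARD4 at 0.70 (SE 0.19). The call of STARD4 ended on leaving out any 1 of 4 libraries, the second or the third of either group (up to 0.0878).

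**Figure D3:**
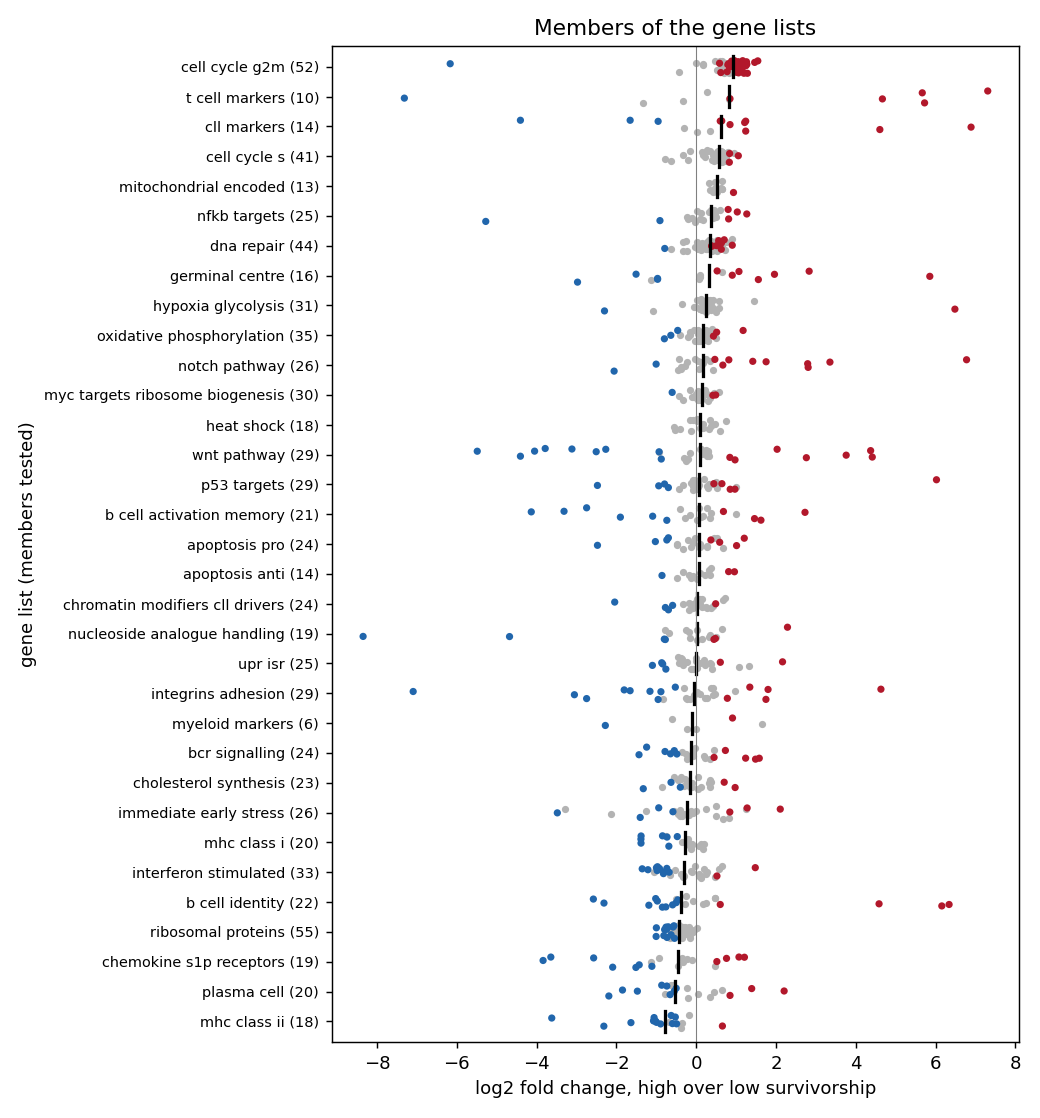
Log2 fold change (high over low survivorship) of each tested member of the 33 gene lists. Points are genes, red where called higher, blue where called lower and grey where not called, and black bars are list medians, which run from -0.79 for MHC class II to 0.93 for G2/M genes.

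Markers of other cell types were read as a check on the gates. Of 10 tested T-cell markers 5 rose and 1 fell (5 and 2 adjusted over the list alone, 5 and 3 with the block). ICOS, a costimulatory receptor, rose from 0.318 ± 0.106 to 50.8 ± 6.08 CPM. The T-lineage transcription factor gene BCL11B rose from 0.352 ± 0.0127 to 8.99 ± 0.875 CPM, and CD4 from 0.0550 ± 0.0280 to 2.98 ± 0.3999 CPM. CD28 fell, with 1 count over the high survivorship libraries and 218 over the low survivorship libraries, a normalised ratio of 218.9 (exact 95% counting interval 38.9 to 8690). CD3E stood at 0.440 ± 0.0963 and 0.251 ± 0.110 CPM. LCK and TRAC were expressed in both groups, LCK at 104.1 ± 25.7 and 85.6 ± 7.39 CPM and TRAC at 123.0 ± 16.1 and 155.8 ± 13.9 CPM (high and low survivorship; TRAC edgeR adjusted p = 0.1163, 0.00756 with the block). The T-cell list had a camera adjusted p of 0.0423 with the preset correlation (0.0954 with the block), and the adjusted p = 0.797 with an estimated correlation. The call ended without the first (0.0706) or the third (0.0516) high survivorship library. Of 6 myeloid markers CST3 rose by 0.91 (SE 0.17) and CD68 had a log2 fold change of -2.28 (SE 0.27). Adjusted over the list alone 2 rose and 1 fell (2 and 1 with the block). VCAN, at 0.339 ± 0.0829 and 0.105 ± 0.0983 CPM, had an edgeR adjusted p of 0.0714 over all genes and 0.0237 with the block. Of 4 natural killer cell markers tested, PRF1, KLRD1 and NKG7 rose by 4.004, 3.33 and 1.35 and NCR3 stood at 0.202 ± 0.148 and 0.167 ± 0.0278 CPM. Of 4 fibroblast markers tested (ACTA2, COL1A1, PDGFRB, FN1) edgeR called 0, with adjusted p-values from 0.0747 to 0.773 and 2 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 2, and with the block ACTA2 and COL1A1 were called (0.0173 and 0.00847). The 1 tested erythroid or platelet marker, GP1BA, had a log2 fold change of -1.44 (SE 0.30).

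Over the 33 lists tested, camera with the preset correlation called 8, 5 up and 3 down. With an estimated correlation it called 0 (smallest adjusted p = 0.797, and 0 at an unadjusted p under 0.05). The estimated correlation was 0.859 for the G2/M and 0.933 for the ribosomal protein list. Values that high leave the test little power, so a missing call there does not show that these lists were unmoved. Fry, which tests whether a list's own genes move one way on balance, called 11, and 9 with the block. In both fits it called the MHC class I and II, T-cell, CLL marker, Notch, integrin and chemokine receptor lists. Adjusted p-values without and with the block were 0.0113 and 0.0424 for CLL markers and 0.00634 and 0.0419 for Notch. They were 0.00929 and 0.0419 for integrins and 4.46e-05 and 0.0274 for chemokine receptors. Fry called the G2/M list in neither fit (0.115 and 0.0951). The block ended the fry calls of the plasma cell (adjusted p = 0.0167, 0.0951 with the block), germinal centre (0.0021, 0.272), nucleoside (0.0267, 0.0951) and Wnt lists (0.0429, 0.0951), with the germinal centre direction up without the block and down with it. It made those of the ribosomal protein (0.162, 0.042) and p53 target lists (0.273, 0.0348). Of the 10 ways to split the 6 libraries into groups of 3, 6 gave at least 8 camera calls, the real split included. A list call alone thus does not set the groups apart from other splits. Every other split put libraries of both sorts on each side and kept part of their difference, so the splits do not measure chance. The median, the mean and camera's direction did not share 1 sign for the B-cell identity, nucleoside, Wnt, immediate early, unfolded protein response, myeloid, activation and memory, chromatin and pro-apoptotic lists. Camera adjusted p-values of the uncalled lists lay between 0.0941 and 0.985. Counts adjusted over the list alone equalled those over all genes where they are not given. For comparison, edgeR called 5552 of all 18476 tested genes, 2468 higher and 3084 lower. Without the block, the S phase, DNA repair, ribosomal protein and oxidative phosphorylation lists, among others, had a smaller share of genes called than that. With the block edgeR called 9690 of the 18476 genes. As rises and falls it called 33 and 3 of 41 S phase and 26 and 4 of 44 DNA repair genes. It called 44 and 0 of 55 ribosomal protein genes, and each of these lists had a larger share called than all genes. The oxidative phosphorylation list, with 12 and 5 of 35, had a smaller share.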

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

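The fits with the length and GC correction, without mitochondrial and ribosomal protein genes, on genes with whole expected counts, and with the block and an estimated correlation were chosen after seeing the data. The replicate block raised the count of genes called to 9690 (4770 higher, 4920 lower), and with the length and GC correction to 9762 (4879 higher, 4883 lower), while the count changed at least 2-fold stayed within 1.5 times of 3784. Leaving out a library or a collection gave 2292 to 6077 genes called (1077 to 2836 higher, 1215 to 3241 lower) and 2244 to 3980 changed at least 2-fold (1063 to 1772 higher, 1181 to 2236 lower); the lowest values came without collection 3. A filter of 1 CPM left fewer genes to test and 2400 changed at least 2-fold (991 higher). The log2(TPM + 1) scale, which shrinks low genes, gave 2047 (833 higher, 1214 lower). Camera called 0 lists with an estimated correlation, 0 with the block and an estimated correlation, 5 without mitochondrial and ribosomal protein genes, which removes both lists, and 4 on genes with whole expected counts, against 8; beyond the lists removed the cause was not tested. RLE scaling, upper-quartile scaling, no filter, limma-voom, limma-trend on log2(TPM + 0.1) and DESeq2 kept the counts of called genes within 1.5 times. DESeq2 called 6349 genes and left 3 with no adjusted p. Direction was compared only for genes called in both the main and the alternative fit. None of the main calls was called in the opposite direction in any of these fits. CXCR4 and ITGB2 kept direction and call in each. For the 125 named genes, 2582 of 2718 alternative values kept the call or its absence, 98 lost the call, 38 gained it and 0 reversed. For lists, judged by the direction and call of the list test, the counts were 685 kept, 51 lost and 18 gained. A changed direction counted as reversed only where either fit made a call, and otherwise as kept. Beyond the values printed with the results, the block changed no other call of a gene named by the rule or of a list. The fits that leave out a library had no block and break a pair. Genes named by the rule whose call ended there were still called in the fit with the block and all libraries. Effective lengths were the same in every library, so the planned effective length offset was not run. In simulated data the fit recovered 3% of genes changed 1.5-fold and 32.8% of those changed 2-fold. The simulation changed 200 genes, while 5552 were called in the data, and the adjusted threshold is stricter when few genes change. Its libraries were also not paired by collection. These rates therefore do not give the share of changes missed here, though calls of changes up to 2-fold may be incomplete. The effect of depth was not tested.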

Other observations

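Gene families were grouped by symbol after the values were seen, 16 of them, and are given as counts of edgeR calls. Fisher's exact test was run on them and is not used, because the families were chosen from the same values. Of 7 GIMAP genes, GTPases of lymphocyte survival, 6 fell and 0 rose, GIMAP8 from 60.7 ± 7.40 to 17.5 ± 2.38 CPM and GIMAP4 from 8.45 ± 0.642 to 0.156 ± 0.151 CPM (low and high survivorship). Of 25 cadherin and protocadherin genes 11 rose and 4 fell, PCDH15 from 0.0916 ± 0.0151 to 17.8 ± 4.25 CPM and CDH11 from 0.272 ± 0.0485 to 9.20 ± 3.66 CPM. Of 20 collagen genes 1 rose and 9 fell, COL21A1 from 21.2 ± 2.52 to 0.537 ± 0.186 CPM and COL24A1 from 28.3 ± 10.8 to 2.91 ± 0.603 CPM. Of 32 interleukin receptor genes 8 rose and 10 fell, with IL18R1, the partner of IL18RAP, from 5.33 ± 0.766 to 109.7 ± 19.0 CPM and IL6R from 20.6 ± 5.94 to 3.96 ± 0.476 CPM. Of 28 genes of the tumour necrosis factor and receptor superfamilies 5 rose and 10 fell, with TNFSF4, the OX40 ligand, from 8.05 ± 2.92 to 299.1 ± 59.3 CPM and TNFRSF21 (DR6) from 155.9 ± 16.6 to 20.2 ± 3.37 CPM. For these families the share of other genes called was 30%. In the others, as rises and falls, edgeR called 68 and 89 of 302 LINC RNAs, 57 and 102 of 472 zinc finger genes named ZNF, 38 and 101 of 417 antisense RNAs and 21 and 38 of 214 solute carrier genes. It called 3 and 12 of 47 TRIM genes, 8 and 11 of 37 potassium channel genes, 5 and 8 of 32 receptor genes named GPR and 2 and 7 of 18 MAGE genes. It called 3 and 1 of 8 HOX genes, 0 and 4 of 8 toll-like receptor genes with CD180, and 3 and 3 of 7 Fc receptor-like genes. For this second set of families the share of other genes called lay between 29.7% and 30.1%. Near it were the 27.6% called of solute carrier, 31.9% of TRIM, 33.3% of antisense and 33.7% of ZNF genes.

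In a scan of the genome that was chosen after the values were seen, with the median of the expressed genes taken off, medians of 31 neighbouring expressed genes passed the 95th percentile of 1000 permutations of gene order (0.441) in 1 region, on chromosome 6, of 27 windows centred from SKIV2L to HSD17B8 (31959080 to 33206831). Its lowest window, from RNF5 to ZBTB22 (32178354 to 33317942), had a median shift of -0.78 in the high survivorship cells (permutation p = 0.001, the smallest the permutations can give). This window holds MHC class II genes. Without taking off that median, its 15 MHC list or HLA genes had a median log2 fold change of -0.84 with 9 falls, and its 16 other genes a median of -0.57 with 9 falls and 0 rises. The highest window, on chromosome 10, reached 0.38 (permutation p = 0.222).

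Of the tests below, those on immunoglobulin segments, on neighbouring silent genes and on T cells were set after the result was seen. Of genes at 3 counts or fewer over one group and at least 1 CPM in every library of the other, 27 were silent in the low survivorship cells (14 protein-coding) and 20 in the high survivorship cells (10 protein-coding). MMP3 and ZNF521, with 0 counts in the low survivorship cells, were at least 209.7-fold and 169.4-fold higher in the high survivorship cells (3 counts over the group), and PDGFRL (855 against 1 count) had a ratio of 851.5 (exact 95% counting interval 152 to 33700). In the other direction ALOX5 (797 against 2 counts) had a ratio of 400.1 (110 to 3310) and CD28 (218 against 1) of 218.9 (38.9 to 8690). A B-cell clone of another origin in one sort is argued against, since IGHV1-2 took at least 96.43% of heavy chain variable reads in all 6 libraries, though that share does not address cells without immunoglobulin transcripts. In the 10 expressed genes around each of 44 silent genes, the median shift toward the silent gene was 0.082 (95% bootstrap interval -0.019 to 0.133). This argues against gain or loss of regions that take in most of those 10 genes as the general cause. A region that reaches only a few of them would not move their median. Silent genes were left out of the 10, so a full loss shared with a neighbour is not seen. Shorter regions stay open, since 9 of 46 placed silent genes had another gene silent in the same sort within 200 kb. Silent in the high survivorship cells were ARHGEF34P, OR2A9P and AC004889.1 on chromosome 7 (144194858 to 144300934) and ANKRD62P1 and VWFP1 on chromosome 22. Silent in the low survivorship cells were MMP3 and WTAPP1 on chromosome 11 and AC007278.1 and AC007278.2, which lie within IL18RAP. MMP3 overlaps WTAPP1 and ARHGEF34P overlaps AC004889.1, so these pairs are not separate neighbours. IL18RAP itself held 59 counts over the low survivorship libraries and was not silent by this rule. Loss of single genes and stable differences in gene regulation between the sorted subpopulations stay open; on-off regulation may account for the pattern and was not tested.

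The G2/M rise and the ribosomal protein fall were weighed together. Length and GC content bias is argued against as the whole cause, since with the correction and the block the list medians were 0.929 and -0.383, and so is a single deciding collection, since leaving out each collection gave a G2/M median of at least 0.772 and a ribosomal protein median of at most -0.385. Chance stays open for list calls: 6 of the 10 splits of the libraries gave at least the 8 lists called, the highest other split 13, and among the 4 splits that part all pairs the other 3 gave 10, 6 and 6. For genes called, 1 of 10 splits (the real one) reached 5552, and 1 of 10 reached 3784 changed at least 2-fold. The highest other split gave 0 for both, and 10 splits are too few for a share under 0.05. Every other split put libraries of both sorts on each side, so the sort difference lay within its groups. Those 0 calls therefore do not bear on chance. For lists, such splits keep part of the sort difference, so they leave chance open and cannot measure it. A larger share of dividing cells in the high survivorship sort may account for the G2/M rise, a hypothesis left untested here.

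For the T-cell genes, T cells among the sorted cells are argued against, because CD3D, CD3E, CD3G and CD2 summed to at most 1.32% of the level of ICOS in the high survivorship libraries, while ICOS rose from 0.318 to 50.8 CPM and CD28 fell. TRBC1 and TRBC2 stood at 0.0228 ± 0.0280 and 0.158 ± 0.0259 CPM in these libraries. Expression of single T-lineage genes by the leukaemia cells may account for the pattern, as a hypothesis found on the same data.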
